A study of Homo sapiens with 4 samples.

How the data were processed

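Total RNA of the 4 samples was extracted with TRIZOL and made into libraries with the TruSeq Small RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.3, Trim Galore 0.3.7 and DESeq 1.18.0. The aligner, the miRNA annotation release and the genome build are not given in the sources used here. Per the file headers, the authors deposited for each sample a raw count of reads per pair of precursor and mature miRNA, beside a normalized expression signal. The deposited signal equals the counts divided by 1 size factor per sample (1.94 for both DLL1 libraries, 0.574 and 0.500 for the controls). Each file lists 2813 pairs, of 1881 precursors and 2588 mature miRNAs. A further table deposited by the authors compares the groups, with mean signal per group, a fold change as a ratio, its log2 value, a p-value and an adjusted p-value, per the file headers. No per-sample column was left without a sample.

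From the deposited counts, 1 value was made for each mature miRNA. Where a mature miRNA was listed at more than 1 precursor (167 miRNAs), the highest of its rows was taken, since a read that maps to several precursors can be counted at each. Counting rules can shift the values of miRNAs with near-identical copies. Groups were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr by group with its minimum count of 10, TMM scaling, glmQLFit with robust dispersion and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. The quasi-likelihood fit used the newer dispersion method (legacy off), settled after both had been run, since the alternatives fixed earlier list the older one; the calls numbered 313 and 315. The standard error is the absolute log2 fold change over the square root of the F statistic. CPM values are read counts scaled to the TMM-scaled library size. There was no covariate, as the labels give no batch, date or replicate number.

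The 20 lists of miRNAs, the rule for named miRNAs and the main design were chosen before the data were examined. Every mature arm of a listed name counts as a member. Lists with at least 3 tested members were compared with camera (limma 3.58.1, preset correlation 0.01, log-CPM with a prior count of 2), with camera using an estimated correlation, and with fry. The rule named all tested arms of the miR-221 and miR-222, melanocyte lineage and MITF-targeting lists, the 5 miRNAs with most counts summed over the libraries, the 10 largest changes in each direction among miRNAs with an adjusted p below 0.05, no overlap of the groups and a mean of at least 10 CPM, and the 2 members with the smallest p of each other list. Other members, such as let-7d-3p, let-7b-3p and miR-486-5p, were named after their values were seen. A fold against a group at 0 counts is a bound against 3 counts over the group. Ratios with 1 to 3 counts in the lower group have exact binomial 95% intervals.

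Hairpin coordinates, sequences and overlapping genes came from GENCODE release 29 on GRCh38, matched by name for 1876 of 1881 precursors. As the authors' build is unknown, these locations are those of the reference. The mature sequences were not used here, so GC content is that of the hairpin, or of the part of the hairpin on the side of an arm.

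The alternatives fixed beforehand were RLE, upper quartile and library total scaling, TMM without the 5 most abundant miRNAs, no filter, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, robust dispersion off, the older dispersion method, sums or separate rows for mature miRNAs with several precursors, each library left out in turn, and an adjusted p of 0.1. Chosen after seeing the data were the removal of the lowess trend on hairpin GC as an offset, thinning of the DLL1 libraries to the mean control total of 115564 counts, the authors' size factors, and the restriction to entries numbered below 3000. With that trend taken out, a log2 fold change is the DLL1 over control value relative to that of miRNAs of like hairpin GC.

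The edgeR test was tested on simulated data for this comparison, with counts for the 386 miRNAs drawn from the real means and library sizes and 200 of them changed. It recovered 65.6% of those changed by 1 on the log2 scale, 92.4% of those changed by 2 and 97.0% of those changed by 3, and called 3 of 176 unchanged miRNAs. With no miRNA changed it called 0 of 364. The simulated changes were balanced in direction and unrelated to hairpin GC. In the real data fold changes followed GC and more miRNAs were called, so these rates need not hold there. With fold changes that followed hairpin GC alone, at the slope of the real data, it called 61.0% of 372 miRNAs before the trend was taken out and 0 after. Camera gave a p of 4.21e-18 for a simulated list of 10 miRNAs shifted by 2 and 0.202 for an unshifted one. All other miRNAs were unchanged in that simulation. In the real data the log2 fold changes had an SD of 2.42, so camera need not behave alike there. Python 3.11.15 with scipy 1.17.1 was used for permutation tests and exact intervals.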

Results

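Small RNA was profiled by sequencing in WM3682 cells, a human melanoma line, after 5 days on plates coated with Delta-like 1 (DLL1), a ligand that activates Notch receptors, and on control plates without it. The coating solution held 2 ng/µl of DLL1. Each group had 2 libraries, and the stated question was which microRNAs (miRNAs) change when Notch signalling is activated. The groups were taken from the name given to each sample's source, because the treatment text is the same for all 4 samples and mentions the coated plate for the controls too. No label says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Counted over mature miRNAs, the DLL1 libraries held 710735 and 788931 reads and the control libraries 119853 and 111275. A floor of 3 counts corresponds to 4.88 and 4.56 CPM (read counts scaled to the TMM-scaled library size) in the DLL1 libraries and to 20.8 and 23.7 CPM in the controls, so that a low miRNA was harder to detect in the controls. Intervals and floors here cover counting error only. Within a group, the counts of the libraries differed by more than sampling noise (chi-square per degree of freedom 13.3 for DLL1 and 6.23 for control), and between groups by more still (352 to 442). The Pearson correlation of log2 CPM across miRNAs was 0.957 between the DLL1 libraries, 0.872 between the controls and 0.806 to 0.821 between groups.

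On DLL1 the miRNA profile differed broadly from that of the control plates. miR-21-5p, an abundant miRNA often raised in tumours, rose from 6174 ± 452 to 115393 ± 10011 CPM (SD, n = 2 per group), a log2 fold change of 4.22 (SE 0.17), and became the most abundant miRNA of both DLL1 libraries. miR-10b-5p rose by 2.97 (SE 0.15), miR-22-3p by 1.76 (SE 0.14) and miR-191-5p by 0.82 (SE 0.15) on the log2 scale. miR-92a-3p, a member of the miR-17-92 cluster and the most abundant miRNA of both control libraries, fell from 158763 ± 10582 to 67253 ± 8485 CPM (log2 fold change -1.24, SE 0.15). Values with the trend of fold change on hairpin GC content taken out are relative to miRNAs of like hairpin GC. A negative value among them need not be a fall in CPM. On that scale miR-10b-5p stood at 0.79, miR-21-5p at 3.20 and miR-92a-3p at -2.49. These 5 miRNAs had the most counts summed over the 4 libraries, a sum that the deeper DLL1 libraries dominate (by mean CPM miR-30d-5p, at 47687, lay above miR-22-3p, at 33622), and their adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 2.3e-08 and 0.000665.

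Of 386 miRNAs tested, 313 (81.1%) passed an adjusted p of 0.05 in that test, 161 higher and the others lower on DLL1. Among them 275 changed by more than 2-fold and 162 by more than 4-fold, 95 of those upward and 67 downward. The CPM of the groups did not overlap for 355 miRNAs (92%), where chance gives 33.3%. The balance of directions depended on the filter, the test and the scaling. Against 51.4% of the calls higher in the edgeR test, the share was 64.6% without a filter on low counts, 63.0% with DESeq2 and 59.8% with the authors' size factors, but 43.3% with library totals and 47.9% with upper quartile scaling, where more miRNAs were lower than higher. The spread of log2 fold changes over all tested miRNAs was 2.42 (SD).

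**Figure D1:**
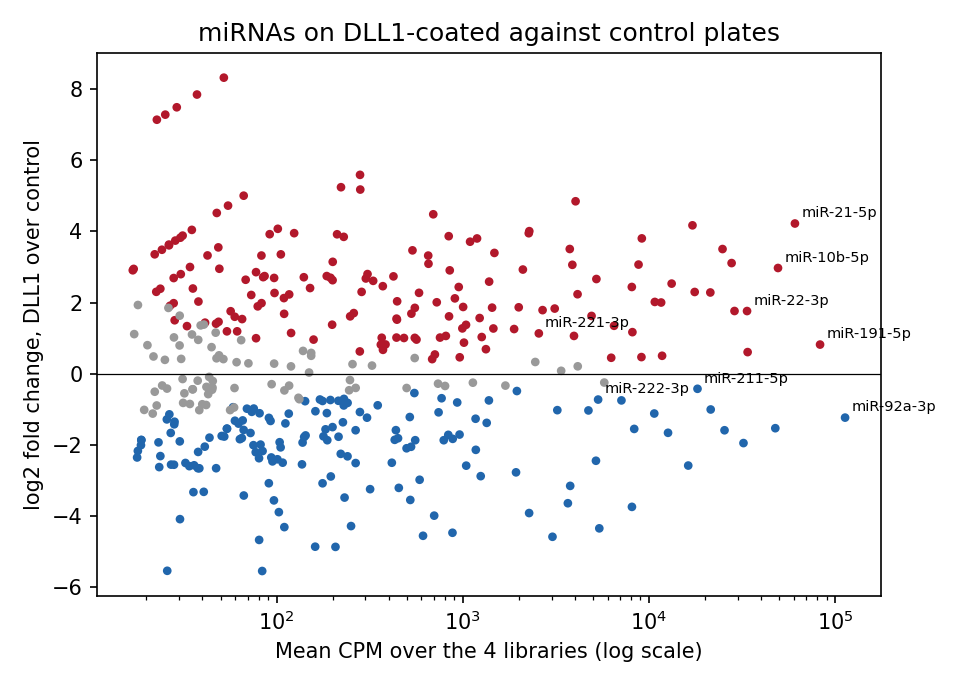
log2 fold change (DLL1 over control) against the mean CPM over the 4 libraries on a log axis, 1 point per tested miRNA, with higher calls in red, lower calls in blue and the others in grey. Both directions occur across the range of abundance, and the 5 uppermost points are fitted values of miRNAs without a count in either control, for which only lower bounds are given in the text.

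The largest rises included 5 miRNAs without a single count in the controls. Against a floor of 3 counts over the control group, miR-96-5p was at least 9.36-fold higher, miR-33b-5p at least 6.73-fold, let-7a-3p at least 5.24-fold, miR-4775 at least 4.54-fold and miR-196b-5p at least 4.11-fold. miR-4775 lost its call with the GC trend taken out (adjusted p = 0.280). miR-98-5p, of the let-7 family, rose from 271 ± 19.9 to 7798 ± 69.6 CPM (SD, n = 2), a log2 fold change of 4.85 (SE 0.18, adjusted p = 2.3e-08, edgeR). Its hairpin lies on chromosome X from 53556223 to 53556341 (GRCh38) in an intron of HUWE1. miR-29b-3p, with 1 and 3 counts in the controls, rose by 5.18 (SE 0.39) on the log2 scale, or by 4.46 and 6.28 without control replicate 1 and 2, and by 2.96 with the GC trend taken out. miR-374a-3p had 3 counts in the controls against 702 on DLL1, a ratio of 49.8 (95% counting interval 17 to 242), and miR-19a-3p had 3 against 550, a ratio of 39.0 (13.3 to 190). miR-153-3p had 1 count in the controls against 164, a ratio of 34.9 (6.17 to 1386). On the log2 scale, miR-98-5p stood at 3.05, miR-374a-3p at 2.29 and miR-19a-3p at 3.45 with the GC trend taken out, where miR-153-3p stood at 3.58.

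Among the largest falls, miR-7704 went from 5824 ± 809 to 241 ± 7.47 CPM (log2 fold change -4.59, SE 0.18, n = 2, adjusted p = 2.3e-08, edgeR) and miR-7110-3p from 10317 ± 2043 to 504 ± 102 CPM (-4.36, SE 0.21). The hairpin of miR-7704 (chromosome 2, 176188843 to 176188901) overlaps an exon of HOXD1, a homeobox gene. miR-6752-3p fell by 4.48 (SE 0.24) and miR-6805-3p by 4.57 (SE 0.23) on the log2 scale. miR-1248, whose hairpin (chromosome 3, 186786672 to 186786777) overlaps the small nucleolar RNA gene SNORA81, fell by 5.56 (SE 0.48), and its reads cannot be told apart from fragments of that RNA in these counts. miR-1248 had 2 and 2 counts on DLL1, below the floor of 3, against 20 and 24 in the controls. miR-4258, miR-504-5p and miR-1908-3p fell by 4.88 (SE 0.32), 4.87 (SE 0.42) and 4.32 (SE 0.40). Taking out the GC trend left miR-7704 at -2.56 and miR-1908-3p at -1.77, miR-6752-3p at -3.02, miR-6805-3p at -3.07 and miR-4258 at -3.52, and put miR-1248 at -8.03. miR-4787-3p had 1 count on DLL1 against 14 in the controls, a ratio of 65.8 in favour of the controls (95% counting interval 10 to 2784), and a log2 fold change of -3.22 with the GC trend out. miR-6756-3p had a log2 fold change of -4.68 (SE 0.97) and control values of 156 ± 171 CPM from 5 and 35 counts. It stood at -5.64 without control replicate 1, was not tested without control replicate 2 and stood at -3.32 with the GC trend out, and it did not pass without the filter on low counts (-4.19, adjusted p = 0.0610, over all alternatives 5.09e-06 to 0.0610).

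The cluster of miR-221 and miR-222 was examined first because the series title names MITF, the transcription factor of the melanocyte lineage, and these miRNAs are linked to it. Its arms did not move together. miR-221-3p rose from 1606 ± 133.2 to 3516 ± 98.9 CPM (SD, n = 2; log2 fold change 1.13, SE 0.15, adjusted p = 5.86e-05 in the edgeR test) and miR-221-5p from 81.2 ± 2.93 to 522 ± 43.6 CPM (2.68, SE 0.26, adjusted p = 6.25e-06). miR-222-3p fell from 6657 ± 1459 to 4007 ± 241 CPM (-0.73, SE 0.17, adjusted p = 0.00262), and miR-222-5p, with 15 and 11 counts on DLL1 and 2 and 1 in the controls, was not tested. All 3 tested arms also passed when adjusted over the list alone. Both hairpins lie on the minus strand of chromosome X (GRCh38, GENCODE release 29), MIR221 from 45746157 to 45746266 and MIR222 from 45747015 to 45747124, in introns of the long non-coding RNA MIR222HG. The fall of miR-222-3p lost its call without the filter (-0.24), with DESeq2 (-0.38), with the authors' size factors (-0.35) and without DLL1 replicate 1 (-0.59) or 2 (-0.61), with adjusted p from 3.85e-05 to 0.460 over all alternatives. With the trend of fold change on hairpin GC content taken out, miR-221-3p stood at -0.084 (adjusted p = 0.655, over all alternatives 1e-12 to 0.655), miR-221-5p at 1.46 (adjusted p = 0.00112) and miR-222-3p at -1.46 (adjusted p = 3.85e-05).

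Of the melanocyte lineage list, 4 arms were tested, of which 1 was higher, 2 were lower and 1 did not pass; adjusted over the list alone, 2 passed. miR-211-3p fell from 164 ± 42.3 to 43.4 ± 7.61 CPM (log2 fold change -1.93, SE 0.35, adjusted p = 0.000559, edgeR). miR-211-5p, whose hairpin lies in an intron of the MITF target TRPM1 (MIR211, chromosome 15, 31065032 to 31065141), fell from 20905 ± 1243 to 15538 ± 1015 CPM (-0.43, SE 0.14, adjusted p = 0.0164). That call was lost under 10 of 21 alternatives, among them the removal of either DLL1 library or of control replicate 2 and the GC trend taken out (-0.13), and the sign turned without the filter (0.063). miR-509-3p rose from 52.0 ± 4.82 to 103 ± 21.8 CPM (adjusted p = 0.0470) and lost its call under 9 of 19, among them the removal of either control library. miR-204-5p, in an intron of TRPM3, did not pass (-0.28, SE 0.16, adjusted p = 0.120). It passed as lower under 5 of 21 alternatives, among them upper quartile scaling (-0.45, adjusted p = 0.0258), library totals (-0.75, adjusted p = 0.00135) and the GC trend taken out (-1.37, adjusted p = 4.08e-05), and stood at 0.097 with the authors' size factors, with adjusted p from 4.08e-05 to 0.885 over all alternatives. As a set the list did not stand apart from the other miRNAs (camera, adjusted p = 0.517). With the GC trend taken out it had 0 higher and 2 lower, and miR-509-3p turned to -0.73 without a call.

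miRNAs reported to target MITF were higher in all 9 tested arms, and in 9 when adjusted over the list alone. Both arms of miR-148a, miR-148b and miR-340 counted, whichever arm the reports concern. The list had 16 arms in the deposited counts. Among those too low to test was miR-218-5p, with 24 and 14 counts on DLL1 and 0 and 1 in the controls. miR-137, also listed, had no count. miR-148a-3p rose from 1222 ± 61.0 to 17083 ± 2217 CPM (SD, n = 2; log2 fold change 3.81, SE 0.17, adjusted p = 7.01e-08, edgeR), miR-101-3p by 3.95 (SE 0.20), miR-340-5p by 4.48 (SE 0.25) and miR-182-5p by 2.02 (SE 0.19). The others were miR-148b-3p (2.59), miR-148b-5p (2.30), miR-148a-5p (1.52), miR-340-3p (ratio 13.2 from 1 control count, 95% counting interval 2.28 to 529) and miR-152-3p (1.19, SE 0.47). Camera with its preset correlation gave an adjusted p of 0.0147 for the list, and an adjusted p = 0.566 with an estimated correlation. Under other scalings 8 or 9 of the arms were higher and 0 lower, miR-152-3p being lost with upper quartile scaling and library totals. Leaving out control replicate 1 left miR-152-3p at 0.56 (adjusted p = 0.378, over all alternatives 0.00294 to 0.378) and miR-340-3p at 2.53, both without a call, and without control replicate 2 miR-152-3p stood at 2.04. With the GC trend taken out, 6 were higher, 0 lower and 3 not called (miR-148b-5p, miR-148a-5p and miR-340-3p), with miR-148a-3p at 2.36, miR-101-3p at 2.16, miR-340-5p at 2.16, miR-148b-3p at 0.86 and miR-152-3p at 1.99.

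**Figure D2:**
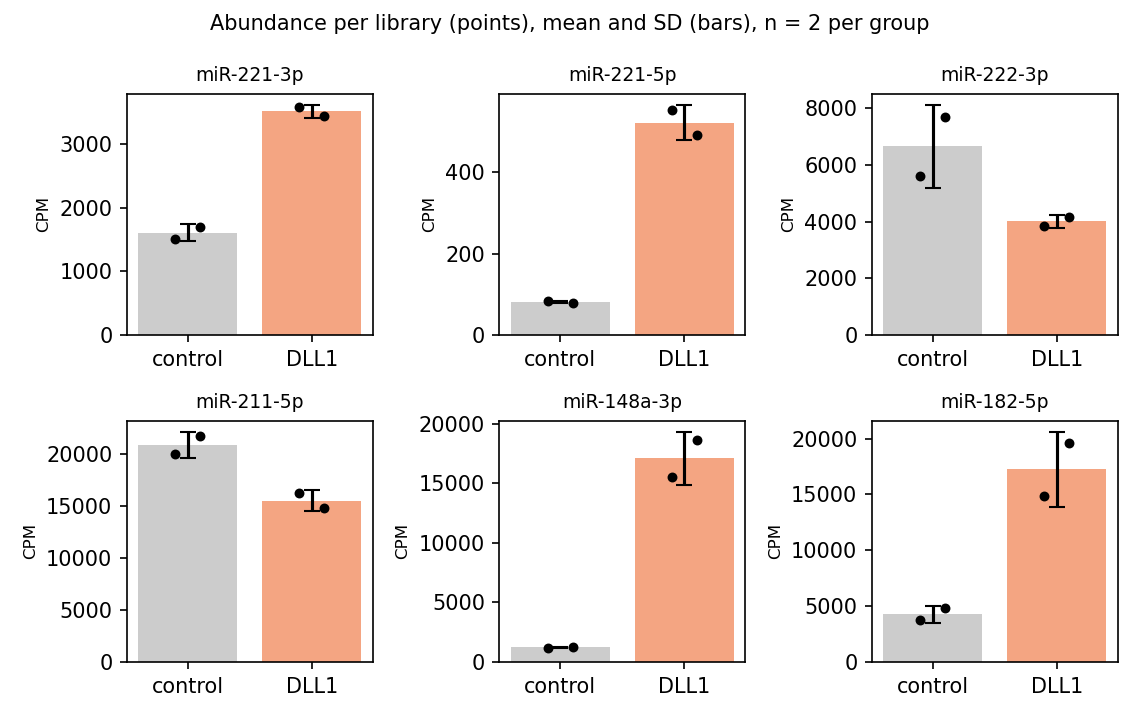
CPM of 6 miRNAs on control and DLL1 plates, with each library as a point and the bar and whisker showing the mean and SD (n = 2 per group, linear axes from 0). miR-221-3p, miR-221-5p, miR-148a-3p and miR-182-5p are higher on DLL1, while miR-222-3p (4007 against 6657) and miR-211-5p (15538 against 20905) are lower, both without a call under some of the alternatives.

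In the let-7 family, which represses growth genes such as HMGA2 and LIN28, 13 arms were tested, 9 were higher, 2 lower and 2 not called, and all 13 passed when adjusted over the list alone. let-7f-5p rose from 1800 ± 172 to 32445 ± 233 CPM (log2 fold change 4.17, SE 0.16, adjusted p = 2.3e-08, edgeR). The arms that fell were the star strands let-7d-3p (-2.59, SE 0.15) and let-7b-3p (-2.08, SE 0.32). Camera gave an adjusted p of 0.0494, with adjusted p = 0.566 with an estimated correlation, and without each library in turn 0.0570 to 0.118. let-7 members differ by few bases, so reads may have been split between them in the authors' counting. With let-7a-3p at its lower bound the mean of the family was 1.87, and its median was 2.27 either way. The cluster of miR-183, miR-96 and miR-182 was higher in all 3 tested arms (miR-183-5p 2.44, SE 0.18; camera adjusted p = 0.127), and the miR-29 family in 4 of 5 (miR-29a-3p 1.83, SE 0.16; camera adjusted p = 0.127). Other higher miR-29 arms had few control counts, 1 and 3 (miR-29b-3p), 2 and 1 (miR-29a-5p) and 0 and 2 (miR-29c-3p). With the GC trend taken out, the let-7 family had 9 higher and 2 lower, with let-7f-5p at 2.16 and let-7d-3p at -3.66. In that fit the cluster of miR-183, miR-96 and miR-182 had 3 higher, with miR-183-5p at 1.47. The miR-29 family had 1 higher and 1 lower there, and miR-29a-3p stood at -1.38.

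None of the remaining groups stood apart in camera, and most held both higher and lower members. In the miR-17-92 and paralogue clusters, 22 arms were tested, 12 higher and 8 lower (20 adjusted over the list alone; camera adjusted p = 0.399), with miR-19b-3p at 2.91 (SE 0.20) and miR-363-3p at 2.23 (SE 0.15) beside the fall of miR-92a-3p. This list had 5 higher and 10 lower with the GC trend taken out, where miR-19b-3p stood at 0.59 and miR-363-3p lost its call (0.24, adjusted p = 0.197). The family of miR-15, miR-16, miR-424 and miR-503 had 4 of 5 higher (4 over the list alone; camera adjusted p = 0.206), led by miR-16-5p at 2.53 (SE 0.15) and miR-15a-5p at 2.80 (SE 0.43). miR-15a-5p, with 18 and 3 counts in the controls, stood at 4.44 and 2.14 without control replicate 1 and 2. Once the GC trend was out, 0 members were higher, 1 was lower (miR-15b-5p, -1.63), and miR-16-5p stood at 0.18 and miR-15a-5p at 0.92. In the miR-23/27/24 clusters 7 of 9 were higher and 1 lower (8 over the list alone; adjusted p = 0.127), with miR-27b-3p at 3.51 (SE 0.18) and miR-27a-3p at 2.66 (SE 0.21). In the miR-30 family 6 of 10 were higher and 2 lower (8 over the list alone; adjusted p = 0.206), including miR-30d-3p at 3.92 (SE 0.38) and miR-30e-5p at 2.44 (SE 0.15). In the miR-99/100 and miR-125 families 4 of 10 were higher and 3 lower (7 over the list alone; adjusted p = 0.768), with miR-100-5p at 1.56 (SE 0.18) and miR-125a-5p at -1.12 (SE 0.15), of which miR-100-5p lost its call with the GC trend out (0.21, adjusted p = 0.341). In the miR-181 family 4 of 7 were higher and 1 lower (5 over the list alone; adjusted p = 0.516), but miR-181a-5p (0.61) and miR-181b-5p (1.06) turned to -0.80 and -0.42 with the GC trend out. Of miRNAs reported to target NOTCH receptors or ligands, 5 of 6 were higher (5 over the list alone; adjusted p = 0.235), with miR-34a-5p, a p53 target, at 2.01 (SE 0.18) and miR-146a-3p at 2.69 (SE 0.44). With the GC trend taken out this list had 1 higher (miR-34a-5p, 1.27), 1 lower (miR-146a-5p, -1.02) and 4 not called, miR-146a-3p among them (1.24). Without control replicate 1 miR-146a-3p stood at 3.34. Of those reported in melanoma invasion, 6 of 9 were higher and 3 lower (9 over the list alone; adjusted p = 0.364), with miR-21-3p at 3.07 (SE 0.15). Of p53 and hypoxia responsive miRNAs, 3 of 6 were higher and 1 lower (5 over the list alone; adjusted p = 0.353), with miR-192-5p at 3.47 (SE 0.22). With the GC trend out, the higher and lower members were 5 and 1 in the miR-23/27/24 clusters, 5 and 3 in the miR-30 family, 3 and 3 in the miR-99/100 and miR-125 families, 4 and 2 in the invasion list and 3 and 0 in the p53 and hypoxia list. In that fit miR-27b-3p stood at 2.31, miR-30d-3p at 2.50, miR-30e-5p at 1.73 and miR-21-3p at 2.04. The miR-181 family had 1 higher and 4 lower in the same fit. Over the scalings it had 1 to 4 higher and 0 to 2 lower. The miR-99/100 and miR-125 families had 3 to 4 higher and 1 to 4 lower over the scalings, with a median from -0.12 to 0.72. The cluster of miR-221 and miR-222 as a set had a camera adjusted p of 0.486. With an estimated correlation, no list passed (lowest adjusted p 0.566). In fry, which tests whether a list's members move on balance one way and does not compare them with other miRNAs, all 16 lists passed.

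Markers of other cell types were few. Of the miR-200 family and keratinocyte miRNAs, only miR-203a-3p was tested. It had 66.0 ± 1.32 CPM on DLL1 and 28.2 ± 28.7 in the controls (log2 fold change 1.15, SE 0.55, adjusted p = 0.0731, edgeR) and did not pass; it passed under 6 of 18 alternatives, reaching 2.97 without control replicate 1. No fibroblast and smooth muscle miRNA and no miRNA of the imprinted 14q32 cluster had enough counts to be tested, with at most 12 and 5 counts in a library. Of the blood cell and endothelial miRNAs, miR-126-5p (3.80, SE 0.20) and miR-126-3p (2.13, SE 0.37) were higher and miR-486-5p was lower (camera adjusted p = 0.437). Of the muscle, liver and neuron miRNAs only miR-9-5p was tested, and it rose by 3.87 (SE 0.24) on the log2 scale. Taking out the GC trend left miR-9-5p at 1.77 and ended the call of miR-486-5p (-0.13, adjusted p = 0.768), so that the blood cell and endothelial list had 2 higher and 0 lower.

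The libraries also differed in their makeup. miRNAs numbered 3000 and above, a class chosen after its values were seen, took 4.11% (exact 95% interval 4.06 to 4.16) and 3.13% (3.10 to 3.17) of the DLL1 reads and 23% (22.8 to 23.3) and 19% (18.8 to 19.3) of the control reads. Of 79 tested in this class, 7 were higher and 55 lower on DLL1, and of the 307 others 97 were lower, 56 were not called and the rest were higher. Log2 fold changes also fell with the GC content of the hairpin across 385 miRNAs, which are not independent replicates (Pearson r = -0.56, Spearman rho = -0.58, 2-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give, adjusted p = 2.5e-05 over 5 relations with GC). The median was 2.70 in hairpins under 40% GC and -2.14 at 70% and above. With the GC trend taken out, 235 miRNAs passed, 111 higher and the others lower than the trend at their hairpin GC. Against that trend, 49 of the 313 turned sign, 18 of them with a call. Of 62 named miRNAs with a call, 45 moved by more than 1.5-fold when the trend was taken out, 12 lost their call and 3 turned sign with a call.

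**Figure D3:**
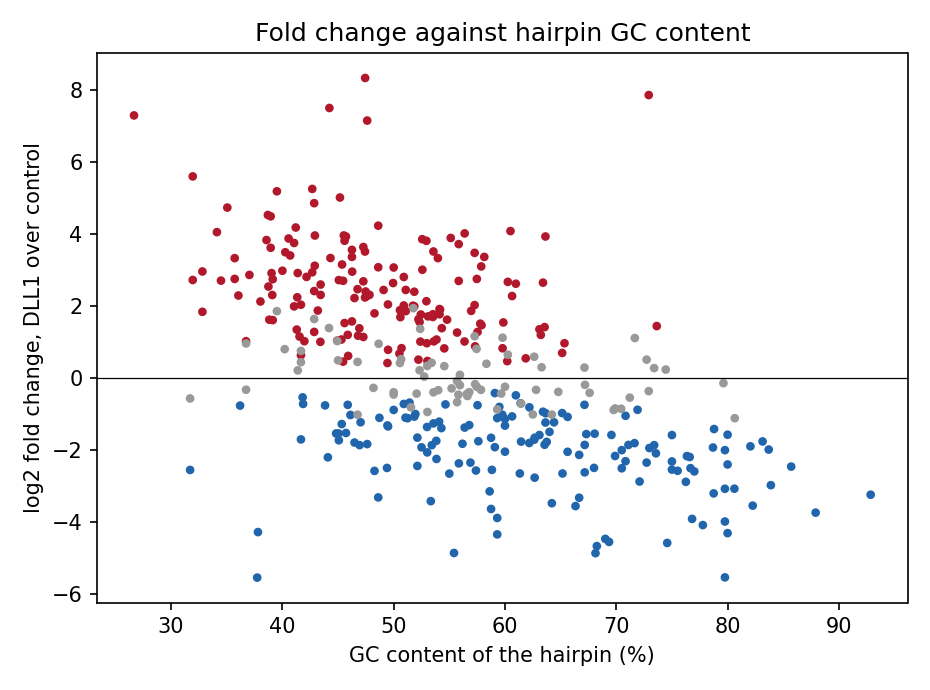
log2 fold change (DLL1 over control) against the GC content of the hairpin in percent, for 385 tested miRNAs coloured as in the plot of fold change against abundance. Rises prevail among hairpins of low GC content (median 2.70 under 40%) and falls among those of high GC content (median -2.14 at 70% and above).

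In the authors' deposited table, 229 of 1488 rows had an adjusted p below 0.05, 74 lower on DLL1 and the others higher, which makes 197 mature miRNAs. All 197 were tested here and passed in the same direction in the edgeR test, and 116 miRNAs passed here alone. In the authors' deposited table miR-221-3p stood at 1.51 on the log2 scale (adjusted p = 2.18e-06), miR-221-5p at 3.06 and miR-222-3p at -0.35 with an adjusted p of 1. Other named miRNAs called here did not pass there. Among them were miR-211-3p (adjusted p = 0.0607), miR-125a-5p (0.0594), miR-152-3p (0.232), miR-509-3p (0.244) and miR-6756-3p (0.685). miR-211-5p, at -0.051, did not pass there either. The authors' fold changes lay above those of the edgeR test by a median of 0.32 on the log2 scale over 439 rows (Spearman rho across rows 0.9999).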

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

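The GC, thinning, size factor and numbering alternatives were chosen after seeing the data. Changed miRNAs numbered 219 (DESeq2) to 345 (mean of at least 10 CPM), within 1.5 times of 313, and with each precursor row kept 365 of 445 rows passed. Leaving out each library in turn gave 236 to 290 changed, where the lone library of a group is assumed to vary like the other group. Fewer were lower without a filter (92) and with DESeq2 (81), and fewer higher with thinned DLL1 libraries (107), where 258 miRNAs were tested. Scaling moved the median log2 fold change by 0.22 (RLE), -0.17 (upper quartile), -0.46 (library totals) and 0.38 (authors' size factors). Lists called numbered 2, against 0 with an estimated correlation, 16 with fry, and 1 to 2 without each library. The authors' table gave 229 calls at 0.05. For 64 named miRNAs, 1245 of 1304 alternative values kept direction and call, 42 lost the call, 11 gained it and 6 reversed. miR-222-3p lost its call without a filter (-0.24), with DESeq2 (-0.38), with the authors' size factors (-0.35) and without either DLL1 library (-0.99 to -0.46 over the libraries left out in turn). Reversed was miR-211-5p without a filter (0.063). With the GC trend out, where signs are relative to miRNAs of like hairpin GC, the reversed ones were miR-221-3p (-0.084), miR-509-3p (-0.73), miR-29a-3p (-1.38), miR-181b-5p (-0.42) and miR-181a-5p (-0.80). The cause was not tested. No paired analysis was possible because the labels carry no replicate numbers. In the controls 3 counts are 20.8 and 23.7 CPM.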

Other observations

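The arms of a hairpin did not always move alike, though pairs of unrelated miRNAs were not set beside them. Of 49 hairpins with both arms listed at 1 precursor and called, 32 had arms that moved in the same direction. The other 17 had arms that moved in opposite directions on DLL1, 14 to 17 under the other scalings, and 11 of 24 with the GC trend taken out. Among them let-7d rose in its 5p arm (1.79) and fell in its 3p arm (-2.59), miR-30d rose in its 3p arm (3.92) and fell in its 5p arm (-1.54, or -2.97 with the GC trend out), and miR-18a rose in its 5p arm (2.71) and fell in its 3p arm (-1.74). The GC trend was taken out by hairpin, which shifted both arms of a hairpin alike. That removal therefore could not test whether GC explains the parting of arms. Neighbouring hairpins also parted. In 7 of 18 genomic clusters with at least 2 called hairpins (5 to 8 under the other scalings, and 3 of 10 with the GC trend out), members moved in opposite directions, each hairpin being represented by its arm of higher mean CPM among those listed at 1 precursor, so that arms shared between precursors, such as miR-92a-3p and miR-16-5p, were left out. The count was also 7 with the arm chosen by total counts or by the mean of either group. Part of this was parting between the arms of a hairpin. miR-18a-5p (2.71), miR-106b-5p (2.61) and miR-30d-3p (3.92) rose like called neighbours, while the arms that represented those hairpins fell. In the cluster of miR-221 and miR-222, both arms of miR-221 rose while miR-222-3p fell, a call lost under 5 of 21 alternatives. With the GC trend out miR-221-3p had no call (-0.084). miR-222-5p, with 15 and 11 counts on DLL1 and 2 and 1 in the controls, was not tested. Whether the arms of miR-222 parted too therefore stays open. In the miR-17-92 cluster on chromosome 13, miR-17-5p (1.27), miR-20a-5p (2.12) and miR-19a-3p were higher while miR-92a-1-5p (-1.12) and miR-18a-3p were lower. Without the GC trend miR-17-5p turned to -0.53 (adjusted p = 0.018), miR-20a-5p had no call (-0.34) and miR-92a-1-5p stood at -2.13. In the cluster of let-7e, miR-99b and miR-125a on chromosome 19, let-7e-5p rose (1.86) while miR-99b-5p (-0.75) and miR-125a-5p (-1.12) fell, but miR-99b-5p turned to 0.50 (adjusted p = 0.0222) with the GC trend out. These miRNAs were picked as examples after their values were seen.

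The tests on hairpin GC, on transcription, on the arms and on the choice of arm here were chosen or reworded after the result was seen. The tests of depth and of overlapping genes were written before.

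Most tested miRNAs differed between the plates, 313 of 386. The thinning test cannot decide on a difference in depth. With the DLL1 libraries thinned to the control depth, 231 of the called miRNAs were still tested. Their median absolute log2 fold change was 2.03 against 1.93, or 105% of its value. Random thinning keeps each miRNA's expected share of the reads, so little change in fold was bound to follow. The values show only that these differences remained at equal read numbers. With the trend on hairpin GC taken out, 60.9% of the miRNAs were still called, against 81.1% before. A smooth trend on hairpin GC therefore did not account for all the calls. Hairpin GC only stands in for the GC of the mature strands, so this cannot decide on recovery that follows the mature strands. Transcription alone is argued against because 34.7% (17 of 49, exact 95% interval 21.7 to 49.6) of the hairpins had arms called in opposite directions. A part played by recovery that follows GC remains a hypothesis: within 23 genomic clusters of 62 hairpins, fold change fell with hairpin GC (r = -0.333, permutation p = 0.0387, adjusted p = 0.0391; r from -0.364 to -0.322 and p from 0.0201 to 0.0473 by the arm chosen), and between arms of 74 hairpins it fell with the GC of their side (r = -0.24, permutation p = 0.0391; rho = -0.27, p = 0.0195, adjusted 0.0326), which is consistent with a technical share. The effect of DLL1 itself, the GC of the mature strands, RNA quality and any difference in library preparation were not tested and stay open, since both controls are the shallower libraries and the labels give no batch.

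Entries with numbers of 3000 and above took 19 to 23% of the control reads and 3.13 to 4.11% of the DLL1 reads. Fragments of other small RNAs or ribosomal RNA in their annotated genes may contribute: 3 of the 79 tested entries (3.80%, exact 95% interval 0.790 to 10.7) overlap such a gene, namely miR-3648 with RNA45SN2, miR-3651 with SNORA84 and miR-7641 with RNA5SP387, and all 3 were lower on DLL1, miR-3648 without a call once the GC trend was out (-0.031, adjusted p = 0.898). The share itself lies under 10%, the bound set beforehand for a share that speaks against this explanation. Its interval, which that bound did not name, reaches above 10%, so the test was taken to leave this open. Fragments from copies elsewhere in the genome were not tested. The search held no nuclear transfer RNA genes, and it counted entries and not reads. miR-7641 alone held 3809 and 3909 of the 27626 and 21191 reads of the class in the controls. On DLL1 it held 9681 and 8365 of 29210 and 24721, a larger part of the class. No biological explanation was tested for this pattern.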
